A study of Caenorhabditis elegans with 2 samples.

How the data were processed

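Gene expression was measured in whole Caenorhabditis elegans hermaphrodites of the wild-type strain N2 at the fourth larval stage (L4). One sample was raised on standard plates (control). The other was raised on plates that held 2 µg/mL of pOPC7, a gallate ester of an oligomeric proanthocyanidin trimer prepared from grape seeds (Vitis vinifera). Exposure covered 48 hours, from the first to the fourth larval stage, at 20 °C per the labels' protocols. Total RNA was extracted with Trizol after bead homogenisation and purified on columns with DNase digestion, and 200 ng was amplified to biotin-labelled RNA, per the labels' protocols. There was 1 array per group (2 in all), so no comparison has a replicate check, no p-value was computed, and the number of arrays limits the precision of every value.

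The deposited table holds 22625 probe sets with 1 value per array. Per the submitters' processing notes the authors used RMA, which subtracts background, quantile-normalises probe intensities and summarises the probes of a set by median polish. The version of RMA, the software and the annotation are not given in the sources used here, and neither is whether a column stands for 1 hybridisation or for several that were averaged. The deposited values ran from 1.78 to 13.90 and were read as log2 values from this range. The columns' medians were 5.94 (control) and 5.99 (pOPC7), so the arrays were close to a common scale but not identical in distribution.

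Probe sets were named through the platform annotation supplied with the table. Of the 22625 probe sets, 20766 had 1 gene symbol, 887 had several and 972 were not named here (77 of these are control probe sets). Entrez identifiers of 20701 singly named probe sets matched a table of WBcel235 genes, and no symbol differed there. A gene's value was the mean over the probe sets that name that gene alone, which gave 17118 genes. Genes with a mean of at least 6 over both arrays were called measured (8059 genes, of which 2001 had several probe sets). The difference was pOPC7 minus control on the log2 scale. Positions of the probes in the genome were not used here.

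Choices made before the data were examined were the measured limit, thresholds of 2-fold and 1.5-fold, 39 gene lists and the rule for named genes. The rule took the 12 measured genes with the largest difference in each direction, leaving out probe sets ending in _x_at, genes whose probe sets disagreed in sign and members of a gene class beyond its first 3. It added up to 4 measured members of each list with the largest absolute difference, and 17 names fixed in advance (fat-5, fat-6, fat-7, hosl-1, sbp-1, nhr-49, nhr-80, acs-2, vit-2, vit-6, gst-4, ftn-1, mtl-1, mtl-2, sod-3, hsp-16.2 and cyp-35A2). Of the symbols typed into the lists, 53 matched no gene of the array under that name and were left out. For each list the median difference of its measured members was set against 10000 random lists of the same size, matched on mean level in 20 bins. The central 95% of those random medians (from the 2.5th to the 97.5th percentile) describes these 2 arrays and is not a test of the treatment. No member of the list of male-specific genes was measured.

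The code was tested on simulated data made from the real levels of the 8059 measured genes with a robust SD of 0.18. All of the genes shifted by 1.5 log2 units passed 1.5-fold, as did 99% of those shifted by 1, while 12 unchanged genes passed. The same SD was used at all levels. It is below the SD of the real differences at levels from 6 to 8 (0.21) and that of a single probe set (0.22). The 12 genes are therefore no estimate of false calls in the real data, where only 2 measured genes differed by 1 log2 unit or more. Of 200 simulated lists of 20 unchanged genes 4.5% fell outside the central 95%, and 99% of lists shifted by 0.2 lay above it.

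Other settings tried were other limits on dim genes (a mean of 5 or 7, no limit, or the brighter array at 6), centring on the median, removing a loess trend on level, leaving out probe sets whose suffix marks possible matches to several transcripts, taking the brightest probe set of a gene, a 1.5-fold threshold, a threshold of 3 local robust SDs, and the mean of a list in place of its median. Settings chosen after seeing the data were these same ones for the 1.5-fold counts and 2 for a shift between low-numbered and high-numbered probe sets, whose dividing number was also chosen from the data. Of those 2, 1 set the median differences of both groups equal (called the shift removed below), and the other left out low-numbered probe sets. Centring does not alter the place of a list among random lists and was left out of counts of settings for lists. The mean of a list in place of its median was left out of these counts too. Leaving out a replicate was not possible. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 (loess with a span of 0.3) and matplotlib 3.10.9.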

Results

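The transcriptome of L4 larvae raised for 48 hours with 2 µg/mL of the grape seed compound pOPC7 was compared with that of unexposed larvae, in a study concerned with how such extracts affect lipids in the nematode. Each condition was represented by 1 array with 22625 probe sets, and 8059 genes were measured. The arrays were very similar. Over the measured genes the log2 values correlated across genes with a Pearson r of 0.991, the differences had an SD of 0.20, and 82.3% of genes differed by less than 1.2-fold. The median difference was 0.04 in favour of the exposed array, and 57.8% of measured genes were above 0. Counts of list members above 0 given below stand against that share, which is not matched on level. The median difference was 0.06 for genes at levels from 6 to 8 and -0.01 for those over 10. A smaller share above 0 is therefore usual in bright lists. Spiked-in hybridisation controls, which are added in equal amounts, differed by 0.01 ± 0.10 (mean ± SD over 18 probe sets). The poly-A spike-in controls differed by -0.03 ± 0.32 over 27 probe sets and by -0.06 ± 0.19 over the 6 with a mean of at least 6.

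The gene with the largest difference was mdl-1, which encodes a Mad-family transcriptional repressor. Its value was 8.63 in the control and 9.84 with pOPC7, a difference of 1.21 or 2.32-fold, on a probe set whose suffix marks matches to several transcripts. Only 1 other measured gene passed 2-fold, C35B1.3 (difference 1.18), whose probe set is of the _x_at kind and which was chosen after its values were seen. No gene was lower by 2-fold. At 1.5-fold, 59 genes were higher and 17 were lower in the exposed array, together under 1% of those measured (99.1% lay within 1.5-fold). The surplus of higher genes depended on the scaling. After centring on the median the counts were 41 higher and 30 lower, and after removal of a trend with level they were 33 and 34.

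Among the genes highest in the exposed array after mdl-1 were hpo-15 (0.99), F45D3.3 (0.95) and nhx-9 (0.92), which belongs to the sodium/proton exchangers. The probe sets of hpo-15 and F45D3.3, like those of the lower genes pyc-1, cnc-7, melo-2, ftn-1 and chc-1, also carry a suffix that marks several transcripts, and without such probe sets no gene was higher by 2-fold. T27F6.8 and dct-7 were each higher by 0.83, the small peptide gene nspe-1 by 0.82 and T01G1.2 by 0.79. The nuclear hormone receptor gene nhr-19 (0.78), the C-type lectin gene clec-247 (0.75), K02A2.5 (0.74) and the nucleoside transporter gene ent-4 (0.74) completed the 12 largest. On the other side stood pyc-1, which encodes pyruvate carboxylase, with 9.29 in the control and 8.52 with pOPC7 (difference -0.77). The DNA repair endonuclease gene mus-81 (-0.76), the ligand-gated channel gene lgc-34 (-0.76) and melo-2 (-0.73) were next. The antimicrobial peptide gene cnc-7 differed by -0.71, with -0.91 and -0.51 in its 2 probe sets. The cell cycle gene emb-27 (-0.71), F44A6.4 (-0.70), the mitochondrially encoded cytochrome b gene CYTB (-0.68), the ferritin gene ftn-1 (-0.67), the mRNA decapping gene edc-3 (-0.66), the clathrin heavy chain gene chc-1 (-0.62) and F02E9.5 (-0.62) followed.

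**Figure D1:**
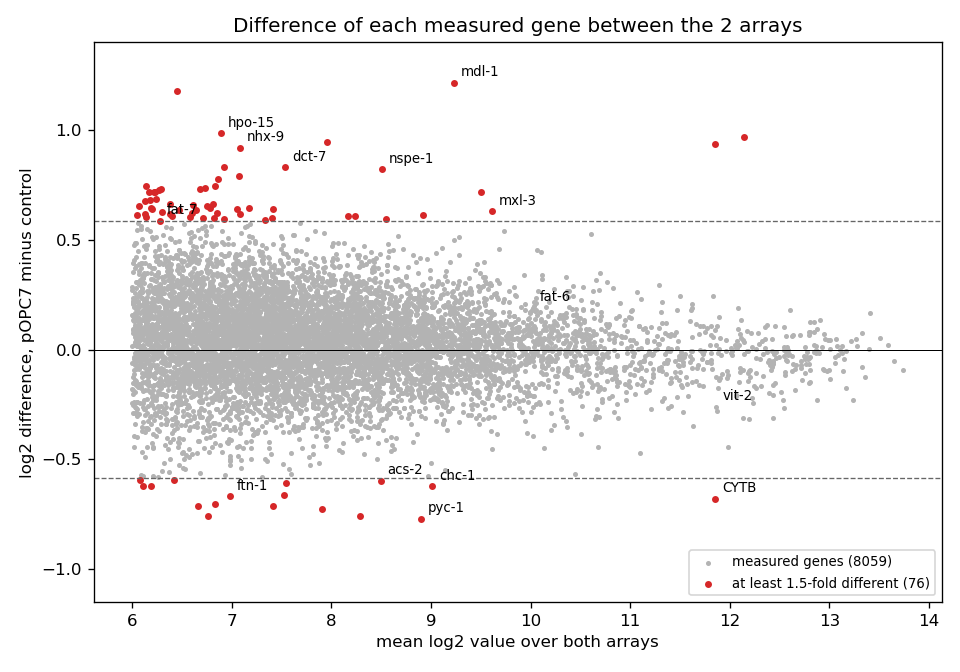
Log2 difference between the pOPC7 and the control array (vertical axis) against the mean log2 value of both arrays (horizontal axis) for 8059 measured genes, with the 1.5-fold limits dashed, the genes beyond them in red and some genes named. Of the red genes 59 lie above and 17 below, and mdl-1 is highest at 1.21.

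These gene values carry a large error. For 1721 genes with at least 2 measured probe sets, the differences of the first and second probe set correlated across genes, which are not independent replicates, with r = 0.08 (Spearman's rho 0.07), and their disagreement corresponded to an SD of 0.22 for a single probe set. All 59 genes higher by 1.5-fold and 13 of the 17 lower ones rested on a single probe set, against 75.2% of all measured genes. Of the 33 measured genes named here that have several probe sets, 5 had probe sets of opposite sign, which were hlh-30 (-0.73 to 0.08), gld-1 (-0.70 and 0.08), ced-1 (-0.58 and 0.08), dnj-20 (-0.40 and 0.03) and pho-1 (-0.01 and 0.35). Others differed widely in size, such as gpd-3 (-0.55 and -0.02), dim-1 (-0.54 and -0.09) and hsp-110 (-0.49 and -0.04). The differences of single genes given here are therefore values of these 2 arrays and not established changes.

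**Figure D2:**
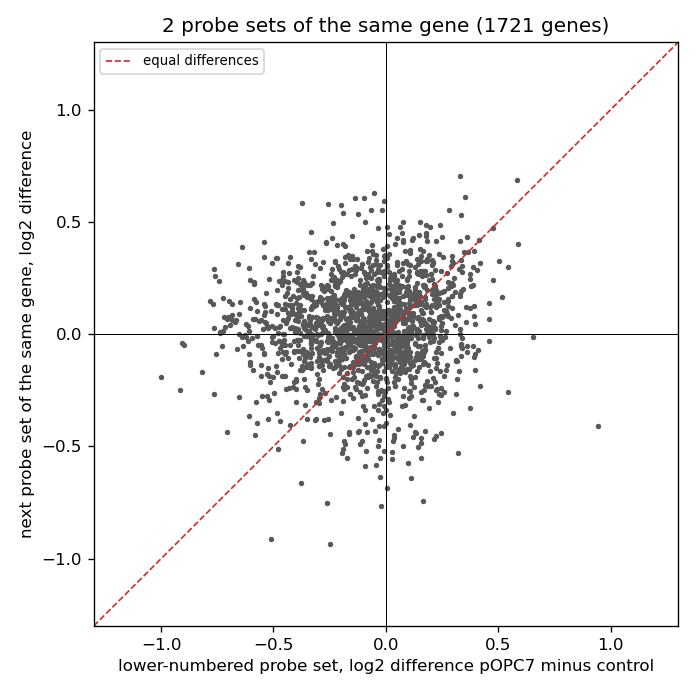
Log2 difference (pOPC7 minus control) of a gene's lowest-numbered measured probe set (horizontal axis) against that of its next probe set (vertical axis), with 1 point for each of 1721 genes and a dashed line for equal differences. The points scatter around 0 with little slope (r = 0.08).

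Lipid metabolism was the stated subject of the study. Of the 6 measured fatty acid desaturases, which introduce double bonds into fatty acids, only fat-7 reached 1.5-fold. This stearoyl-CoA desaturase gene had a value of 5.98 in the control and 6.57 with pOPC7 (difference 0.59), close to the lower limit of measured levels, and did not reach 1.5-fold after centring on the median (0.55). Its close homologue fat-6 was higher by 0.19 (9.93 and 10.12) on a probe set whose suffix marks matches to several transcripts, fat-3 was higher by 0.15, and the omega-3 desaturase gene fat-1 was lower (-0.30). The palmitoyl-CoA desaturase gene fat-5 lay below the measured level, at 5.40 and 5.43. The list's median difference of 0.12 was inside the central 95% of random lists (-0.13 to 0.17).

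Genes of fatty acid elongation and synthesis were higher as a list. Their median was 0.13, above the central 95% of random lists (-0.07 to 0.11), and 13 of 18 were above 0, although none reached 1.5-fold. The elongase genes elo-7 (0.37), elo-4 (0.23) and elo-2 (0.19) and art-1 (0.27), a predicted enoyl-CoA reductase gene, differed most. sbp-1, the worm's SREBP regulator of lipid synthesis, differed by 0.03. The list fell inside the random range in 4 of 9 other settings, with a lowest percentile of 89.9.

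The 35 measured genes of fatty acid beta-oxidation had a median difference of 0.09, inside the random range (-0.04 to 0.09). The acyl-CoA synthetase gene acs-2, a target of the nuclear receptor NHR-49 that feeds fatty acids into mitochondrial oxidation, went from 8.80 to 8.20 (-0.60, or 0.66-fold). Its 2 probe sets disagreed in size, and the brighter one alone gave -0.19, which is short of 1.5-fold. ech-2 (0.43), acox-1.5 (0.35) and acdh-3 (0.34) were higher by less than 1.5-fold, and nhr-49 itself differed by -0.19. Among regulators of fat metabolism, the transcription factor gene mxl-3 was the only one of 22 measured to pass 1.5-fold (9.29 in the control, 9.92 with pOPC7, difference 0.63). nhr-48 (0.52) and nhr-23 (0.50) were higher, nhr-68 lower (-0.38), and nhr-80, which regulates desaturase genes, differed by 0.15.

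Lipases showed no shared direction. The 11 measured members had a median of -0.01 and none reached 1.5-fold, with lipl-7 (-0.23), lips-10 (-0.16) and lips-7 (-0.12) lower and lid-1 (0.20) higher. The hormone-sensitive lipase gene hosl-1 was below the measured level (5.55 in the control and 5.72 with pOPC7), and its 2 probe sets had opposite signs (0.45 and -0.11). The triglyceride and lipid droplet list had a median of -0.07, inside the random range (-0.07 to 0.15). It was -0.15 and below the range with a mean of at least 7, and 0.06 without probe sets whose suffix marks several transcripts. Its members went both ways, with acs-4 (-0.32) and acl-5 (-0.27) lower and acl-6 (0.35) and ldp-1 (0.31) higher. Fatty acid binding proteins had a median of -0.07 over 8 genes, from lbp-6 (-0.14) and lbp-7 (-0.11) to lbp-1 (0.14) and lbp-4 (0.17). In the phosphatidylcholine and one-carbon list (median 0.11, random range -0.09 to 0.12) the choline kinase gene ckb-2 was higher by 0.35, ckb-1 and pcyt-1 by 0.13 each, and the methyltransferase gene pmt-1 was lower (-0.24). The yolk protein genes vit-1 (-0.39) and vit-2 (-0.26) were lower while vit-5 (0.03) and vit-6 (0.07) differed little.

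**Figure D3:**
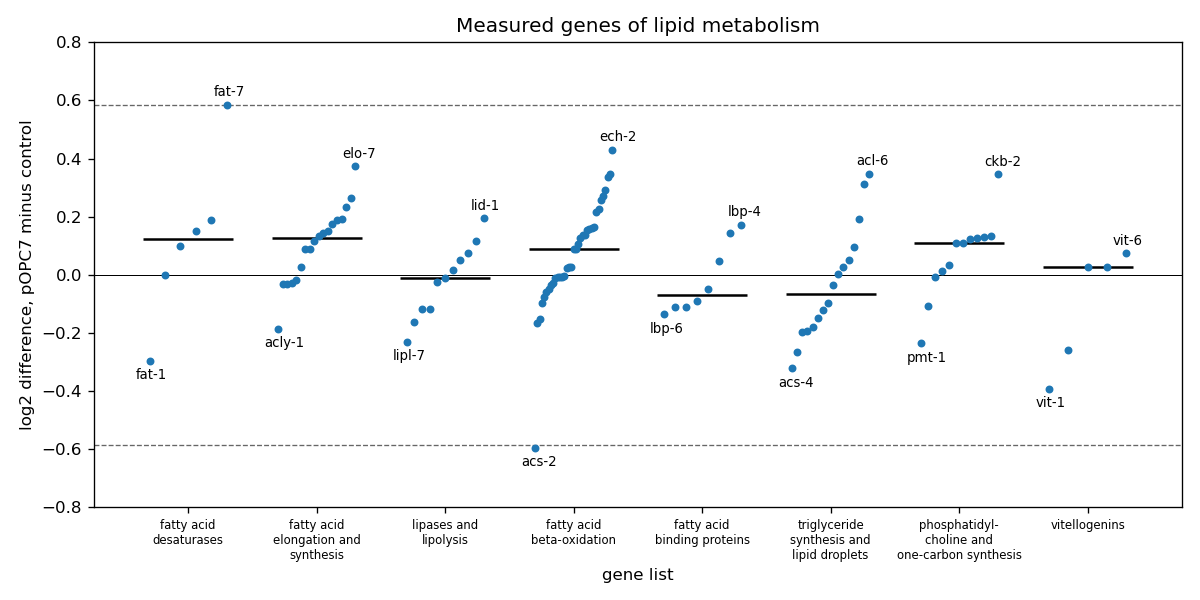
Log2 difference between the pOPC7 and the control array (vertical axis) for each measured gene of 8 lipid lists (points), sorted within the list, with each list's median as a black bar, the 1.5-fold limits dashed and the extreme genes of each list named. Only fat-7 (0.59) and acs-2 (-0.60) reach the limits.

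Central carbon metabolism was lower as a list, with a median of -0.06 over 33 genes against a random range of -0.05 to 0.08, and 13 genes above 0. The trehalose synthase gene tps-2 (-0.36), gpd-3 (-0.29) and the hexokinase gene hxk-1 (-0.27) were lowest and hxk-3 (0.31) was highest. The list fell inside the random range in 3 of 9 other settings, and its median was 0.01 without the low-numbered probe sets. With the medians of low-numbered and high-numbered probe sets set equal it was -0.06, below the range, but this removed only part of the shift seen within genes. The respiratory chain had a median of -0.02 over 47 genes, inside the random range, with nuo-6 (-0.45), nuo-4 (-0.30), asb-1 (-0.29) and mev-1 (-0.29) differing most.

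The lists of genes that handle foreign compounds and stress had medians inside their random ranges, ABC transporters lying above theirs in 1 of 9 other settings. The SD of the members ranged from 0.11 (ER and mitochondrial list) to 0.26 (cytosolic heat shock), against 0.20 for all measured genes. None of 17 measured cytochrome P450s, 19 glutathione S-transferases or 25 ABC transporters reached 1.5-fold, although cyp-14A5 (-0.61) and wht-2 (-0.59) did after centring, and the 3 lists lay inside their random ranges with medians of 0.02, 0.11 and 0.10. The largest differences there were those of cyp-14A5 (-0.57), cyp-43A1 (0.41), cyp-33A1 (0.36) and cyp-35C1 (-0.28), of gst-39 (0.45), gsto-1 (0.30), gstk-1 (0.27) and gst-6 (-0.23), and of wht-2 (-0.55), pgp-9 (0.44), haf-9 (0.38) and haf-2 (-0.37). The often induced cyp-35A2 and gst-4 differed by 0.02 and -0.04. Of 26 measured UDP-glucuronosyltransferases 1 passed 1.5-fold, ugt-13 (0.62), followed by ugt-53 (0.52), ugt-17 (0.42) and ugt-29 (0.32), and the median was 0.00. ugt-13 did not reach 1.5-fold after centring (0.58). The list of oxidative stress genes had a median of 0.00 over 21 genes, with trx-3 (-0.25) lower and dod-24 (0.33) and gpx-1 (0.20) higher. Its lowest member, gsnl-1 (-0.40), is a gelsolin-like gene whose place in this list is doubtful. sod-3 was below the measured level (4.21 and 4.65). Among 13 cytosolic heat shock genes the chaperone gene hsp-70 was higher by 0.61 (0.57 after centring, short of 1.5-fold), hsp-43 by 0.43 and hsp-16.2 by 0.35, hsp-110 was lower (-0.27), and the median was 0.06. In the ER and mitochondrial list (median 0.05) hsp-3 and dnj-10 were higher by 0.23 each, and dnj-20 (-0.19) and pdi-2 (-0.17) were lower.

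The list of metal and iron genes had a median of 0.16 over 13 genes, just above the central 95% of random lists (-0.08 to 0.16), and 10 genes were above 0. The zinc transporter gene cdf-2 (0.41), the copper transporter gene cua-1 (0.24) and cdr-2 (0.23) were highest, and the metallothionein genes mtl-1 and mtl-2 differed by 0.08 and 0.10. The ferritin gene ftn-1, which stores iron and is held low when iron is scarce, ran opposite to the list, with 7.32 in the control and 6.65 with pOPC7 (-0.67), on a probe set whose suffix marks matches to several transcripts. The list fell inside the random range in 6 of 9 other settings.

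C-type lectins, secreted proteins of which many respond to microbes, had the largest median of all lists. It was 0.18 over 43 genes against a random range of -0.03 to 0.10, 34 genes were above 0, and clec-247 reached 1.5-fold. clec-265 (0.57) and clec-236 (0.52) followed, and clec-153 was lower (-0.54, and -0.60 or past 1.5-fold with the level trend removed). Other immune effectors did not share this, with a median of -0.02 over 38 genes, cnc-2 (0.56) and cnc-3 (0.43) higher and cnc-7 lower by 1.5-fold, though no test compared the 2 lists. The list of neuropeptide genes had a median of 0.14 over 40 genes against a random range of -0.03 to 0.11, with 31 above 0. It does not hold all measured neuropeptide genes. Grouped by name, 17 flp genes were measured with a median of 0.19, and 36 nlp genes with a median of 0.04. Within this list nlp-12 (0.36), nlp-7 (0.33) and flp-7 (0.32) were highest and nlp-36 (-0.44) lowest. C-type lectins and neuropeptides each fell inside the random range in 1 of 9 other settings, the lectins with no limit on level and the neuropeptides without low-numbered probe sets. Of 6 measured insulin-like peptide genes daf-28 (0.21) and ins-37 (0.17) were higher and ins-33 (-0.36) and ins-7 (-0.31) lower, and the targets and members of insulin signalling had a median of 0.01, with dod-23 (0.39), dod-24 (0.33) and dod-18 (0.32) after fat-7.

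Lists that follow larval stage and cell composition, other than the neuropeptides above, lay inside their random ranges, with exceptions in other settings. Oocyte genes lay below in 3 of 9 and muscle genes in 1, and collagens and timing and vulva genes lay above in 1 each. Collagens had a median of 0.03 over 113 genes, with rol-6 (0.45), col-41 (0.38), col-12 (-0.44) and col-176 (-0.35) at the extremes, and moulting genes 0.08 over 61, with ptr-8 (0.50), grl-10 (0.48), nas-7 (0.43) and cutl-18 (0.42) highest. Sperm genes, which turn on in the L4, had a median of -0.03 over 68, with nspb-12 (-0.41), fer-1 (-0.36), sss-1 (-0.33) and spe-4 (-0.30) lowest. Oocyte genes had -0.03 over 33, from cbd-1 (-0.32) and oma-2 (-0.27) to perm-2 (0.30) and fbf-1 (0.41). Germline genes had 0.05 over 33, with rec-8 (0.25), mcm-7 (0.23), mes-2 (-0.24) and gld-1 (-0.31), and timing and vulva genes 0.00 over 14, with lin-14 (0.34) and lin-12 (0.24). Muscle genes had -0.02 over 30, with act-4 (-0.35), dim-1 (-0.32), mlc-1 (-0.31) and act-3 (-0.28) lowest, and intestinal markers 0.04 over 24, with elt-7 (0.33), pho-1 (0.17), cpl-1 (-0.19) and cpz-1 (-0.19). No male-specific gene was measured. With no limit on level the 22 on the array had a median of 0.20, inside the random range (-0.04 to 0.22), and with a mean of at least 5 the 2 left, mab-3 (0.51) and ram-5 (0.49), lay above it.

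Ribosomal protein genes had a median of -0.04 over 72, with rpl-8 (-0.27), rpl-41.2 (-0.27), rps-28 (-0.23) and rps-24 (-0.23) lowest, and proteasome genes 0.05 over 38, with rpn-2 (0.23) and pbs-5 (0.23) highest, then rpn-9 (0.17) and pas-2 (0.17). Endocytosis and yolk uptake genes had -0.04 over 24, with chc-1, ced-1 (-0.25) and rme-2 (-0.22) lower and dsc-4 (0.29) higher, inside the random range. Below it lay the common reference genes (median -0.10 over 14, with cdc-42 at -0.34, gpd-3 at -0.29, cyc-1 at -0.21 and tbb-2 at -0.20), autophagy genes (-0.06 over 23, with atg-13 at -0.34, hlh-30 at -0.31, epg-3 at 0.37 and atg-16.2 at 0.33) and histones (-0.05 over 30, with his-67 at -0.33, his-68 at -0.31, hil-4 at 0.28 and hil-1 at 0.66). In all, 4 of 38 lists lay above and 4 below the central 95% of random lists, where 1.9 would be outside by definition. The histone median was 0.08 and that of the reference genes -0.01 without probe sets whose suffix marks matches to several transcripts, both inside the random range. Histones lay inside it in 7 of 9 other settings, autophagy genes in 4 and reference genes in 3. As a sign of RNA quality, the log2 difference between the 3' and 5' control probe sets changed by -0.13 for actin, -0.07 for Gapdh and 0.04 for ubiquitin between the arrays. The difference itself (3' minus 5') was large on both arrays for ubiquitin, at 4.09 in the control and 4.13 with pOPC7. It was 0.54 and 0.47 for Gapdh and 0.05 and -0.09 for actin.

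**Figure D4:**
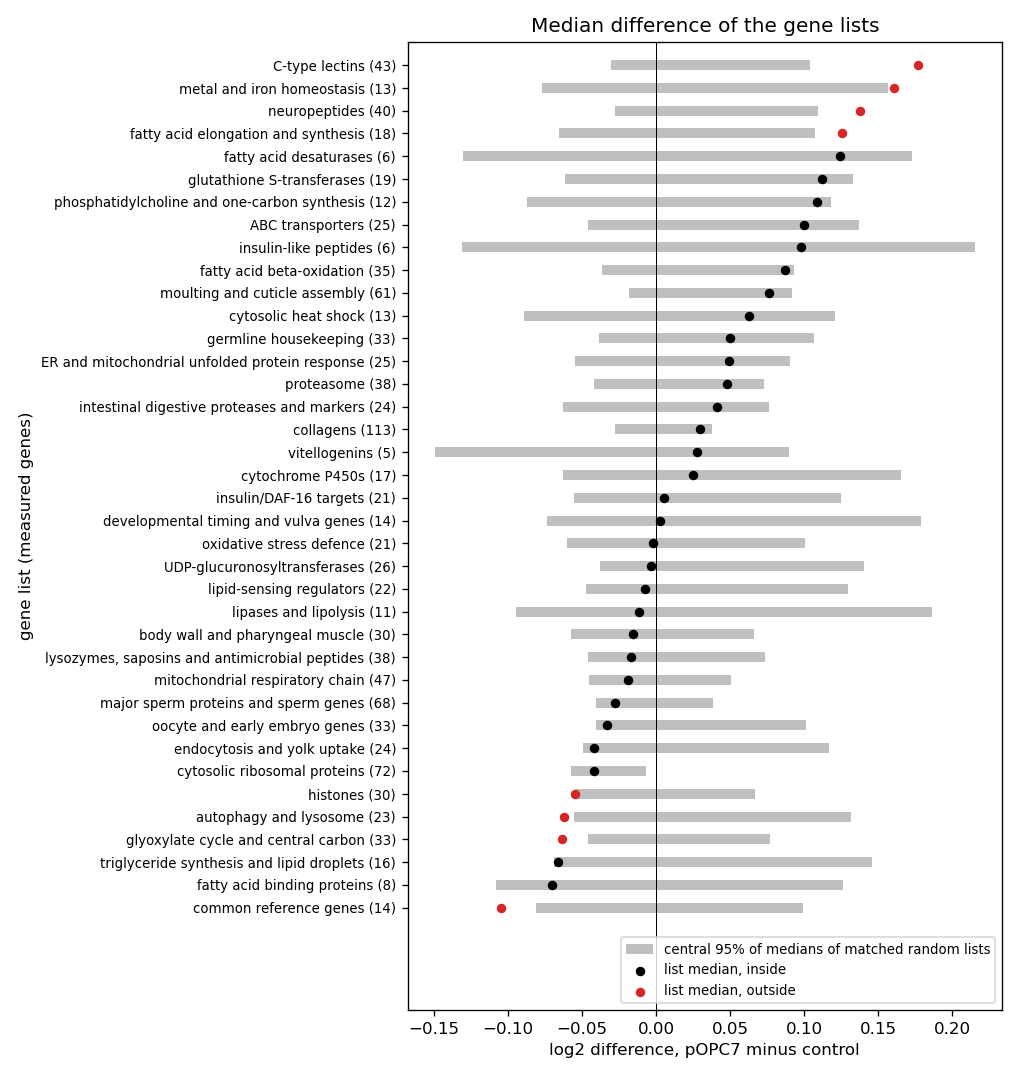
Median log2 difference (pOPC7 minus control, horizontal axis) of the measured genes of 38 gene lists (vertical axis, number of genes in brackets), with the central 95% of medians of 10000 random lists of the same size and level in grey and medians outside it in red. C-type lectins lie farthest above (0.18) and common reference genes farthest below (-0.10).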

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

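The counts and values in this part were chosen after the results were seen.

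Probe sets that carry no gene name here were not part of the comparisons by gene, and some stood above the control array. Of 65 measured probe sets of the _x_at kind without a name, 18 were higher by at least 1.5-fold in the exposed array and 2 lower, with a median difference of 0.26. Of 760 named ones 9 were higher and 1 lower (median -0.01). The 18 had control values from 7.54 to 11.80 and differences from 0.66 to 1.21. Of 310 measured unnamed probe sets 3 were higher by 2-fold and 1 was lower, from 8.42 to 7.32. A pair of _x_at probe sets went from 9.16 to 10.37 (difference 1.21) and from 9.49 to 10.65 (1.16), and a probe set of the _s_at kind from 7.91 to 9.07 (1.16). Both suffixes mark probes shared with other transcripts, so the 18 probe sets may not stand for 18 separate transcripts. The probe sequences were not used here, and no explanation, technical or biological, was tested.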

How the results depend on the processing

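The arrays' small differences left few genes beyond any limit, and counts moved with each choice. Genes higher by 2-fold (2) became 1 with a mean of at least 7, 13 with no filter, 0 without probe sets that may match several transcripts, 35 beyond 3 local robust SDs and 59 at 1.5-fold, and, in settings added after seeing the data, 4 with the numbering shift removed and 1 without low-numbered probe sets. Genes lower by 2-fold (0) became 2 with a mean of at least 5 or the brighter array at 6, 3 with no filter, 45 beyond 3 local SDs and 17 at 1.5-fold. The 1.5-fold counts, whose alternatives were also added afterwards, changed from 59 higher to 120 (mean of at least 5), 20 (7), 333 (no filter) and 33 (loess trend removed), and from 17 lower to 31, 9, 77 and 34 in the same settings, 30 after centring and 28 without probe sets that may match several transcripts. Lists above the random range (4) became 7 with a mean of at least 7, 2 each without multiply matching probe sets, with the brightest probe set and with the numbering shift removed, and 1 without low-numbered probe sets. Lists below it (4) became 2 with the brightest probe set. The histone median turned positive without multiply matching probe sets (0.0821), with the shift removed (0.0251) and without low-numbered probe sets (0.0945), and the central carbon median turned positive in the last (0.0145). The causes of these moves were not tested beyond what each setting removes. The C-type lectin median stayed between 0.11 and 0.18 in all settings and its percentile at or above 96.8, and that of neuropeptides at or above 95.7, while that of the reference genes reached 36.4. Lists inside the random range that lay outside in 1 to 3 of 9 settings were triglyceride and lipid droplets, vitellogenins, lipid regulators, ABC transporters, insulin-like peptides, collagens, oocyte genes, timing and vulva genes, muscle, ribosomal proteins, the respiratory chain and endocytosis. No named gene past 1.5-fold changed sign where a setting gave it a value, but fat-7, hsp-70 and ugt-13 dropped below 1.5-fold after centring (0.55, 0.57 and 0.58) and with the loess trend removed, acs-2 (-0.19) and cnc-7 (-0.51) with the brightest probe set, and fat-7 (0.56) and acs-2 (-0.56) with the numbering shift removed. Without low-numbered probe sets acs-2 also fell short of it (-0.19). Past 1.5-fold came cyp-14A5 (-0.61) and wht-2 (-0.59) after centring and with the loess trend removed, clec-153 (-0.60) with the latter alone, and cnc-2 (0.65) and cyp-14A5 (-0.60) with the numbering shift removed. Among smaller differences ced-1, dnj-20, gld-1, pho-1, sbp-1, cyp-35A2 and vit-5 took both signs. Of the 59 genes higher by 1.5-fold, 39 had a mean under 7, against 28.3% of all measured genes. Filters do not alter a gene's own value. Leaving out a replicate, a paired fit and a pseudocount did not apply.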

Other observations

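Chosen after the results were seen were the scan of gene classes, the test on fasting genes, the picks on the second probe set and with the numbering shift removed, the surplus planted in trend-free values, and the dividing number behind the test of probe set numbering, for which the list medians had also been seen.

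A scan of 65 gene classes with at least 10 measured members, grouped by name, placed 2 classes above and 6 below the central 95% of random lists, where 3.2 would be outside by definition. The FMRFamide-like neuropeptides (flp) had a median difference of 0.19, with 16 of 17 measured genes above 0, and stood beside the C-type lectins at the upper end. The other class of neuropeptide genes, nlp, had a median of 0.04 over 36 genes, with 20 above 0 and 1 higher by 1.5-fold, inside the random range. At the lower end were the zinc transporters of the zipt class (-0.12 over 10 genes), the aldehyde dehydrogenases (alh, -0.09 over 12), core histones (his, -0.07 over 24) and the DnaJ co-chaperones (dnj, -0.07 over 24), with the mixed classes let (-0.07) and lin (-0.04). The scan used the main setting, without removing the shift between low-numbered and high-numbered probe sets described below. Most dnj genes with 2 measured probe sets were below 0 on the lower-numbered one and above 0 on the next. Examples were dnj-25 (-0.56 and 0.07) and dnj-13 (-0.40 and 0.24). Only dnj-14 was below 0 on both (-0.33 and -0.04), and dnj-10 was above 0 on both (0.17 and 0.28). Among let genes let-60 differed in sign (-0.69 and 0.06), while let-711 was below 0 on both (-0.48 and -0.17). The histone list had a median of 0.09 without low-numbered probe sets. Whether these classes would stay low without the shift was not tested.

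For the genes at least 1.5-fold different, 75 genes were picked because their first measured probe set deviated by 1.5-fold from the median of all genes, and another probe set deviated in the same direction in 53.3% (40 of 75, exact 95% interval 41.4 to 65.0), with a median of 0.01 where the first had 0.68. Nearly all of these first probe sets were lower in the exposed array, with Y17G7B.17 (0.65) and Y54F10AM.8 (0.95) as exceptions. The pick therefore says little about genes higher in the exposed array. Probe and hybridisation noise predicts an even split, and the share was 44.2% (19 of 43) without probe sets whose suffix marks several transcripts, 56.8% (25 of 44) with the numbering shift removed and 73.7% (14 of 19, interval 48.8 to 90.9) for genes picked on the second probe set, but the test leaves noise open for the genes named in the report, since all 59 higher genes and 13 of 17 lower ones have a single probe set. A level-dependent trend between the arrays may add the surplus of higher genes, whose share was 49.3% of 67 after a loess trend was removed (interval 36.8 to 61.8), while a surplus of 42 genes planted in trend-free values was still seen after that correction (68.8% higher, median of 100 plantings). A difference in larval timing stays open, since the SD of 173 collagen and moulting genes (0.17) lay at the 16.3th percentile of random lists, within their spread, and an SD does not see a shared shift such as the medians above 0 of both lists (94.1th and 92.0th percentile). Whether the trend is technical, the exposure itself and any other difference between the 2 cultures stay open and untested.

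For the 8 lists outside the random range, the 2740 measured probe sets with the lowest numbers in the array's catalogue had a median difference of -0.05 and the 8431 others 0.06. Within 1299 genes that have both kinds the higher-numbered probe sets exceeded the lower-numbered ones by 0.19 (median), in 74.6% of genes (exact 95% interval 72.1 to 76.9). Differences of this kind between probe sets of one gene may shift lists that hold many low-numbered probe sets, such as central carbon (42.4% of genes against 26.3% of all measured genes). The setting with the shift removed set the medians of the 2 groups (-0.05 and 0.06) equal, which took out less than the 0.19 seen within genes. The central carbon median was -0.06 (0.4th percentile) in that setting, and 0.01 (25.6th percentile) without low-numbered probe sets. Neuropeptides held 30% genes with a low-numbered probe set and lay above their range. C-type lectins, also above theirs, held 11.6%, below the share of all measured genes. After the shift was removed 7 lists lay outside, 5 of the 8 on their former side, and without low-numbered probe sets 5 lay outside, 2 of the 8 (C-type lectins and autophagy) on their former side and vitellogenins, ribosomal proteins and the respiratory chain newly below, which leaves open how much of the pattern the shift accounts for. Neuropeptides stayed outside in the former setting and not in the latter (95.7th percentile), and whether the exposure moved any list was not testable with 1 array each.

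For genes of fasting, acs-2, icl-1 and hacd-1, which are known to be induced when worms starve, differed by -0.60, -0.23 and -0.01, while fat-6, fat-7 and mxl-3, known to be lowered then, differed by 0.19, 0.59 and 0.63. The mean contrast of 0.75 lay at the 100th percentile of random pairs of lists, and the contrast was 0.59 without acs-2 and 0.37 without a limit on level, where of the other genes induced in fasting lipl-1 (0.29), lipl-3 (0.21), lipl-4 (0.25), fil-1 (0.20) and cpt-3 (0.15) were higher and lipl-2 (-0.17) and fil-2 (-0.27) lower. The gene that this setting added to those lowered in fasting, fat-5, differed by 0.02. Probe sets whose suffix marks matches to several transcripts are argued against as its whole source, since acs-2, fat-7 and mxl-3 have none and the contrast without such probe sets was 0.91 (4 genes), although its place at the 99.99th percentile is no independent evidence of the pattern, as these 3 genes prompted it. Whether the exposed larvae differed in feeding state stays open, because the genes were listed after acs-2, fat-7 and mxl-3 had been seen and only 6 were measured.

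On 445 probe sets the deposited values of both arrays were equal to the last digit given.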
